A study of Mus musculus with 43 samples.

How the data were processed

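Total RNA from mouse brain was sequenced in 43 libraries, prepared per the labels' protocols with a Sepasol extraction and the MGIEasy RNA Directional Library Prep Set on an MGISP-960 system. Transcript abundance was estimated with Salmon on the mouse genome GRCm38 (mm10), per the submitters' processing notes. The version of Salmon, the annotation release and the reference sequences are not given in the sources used here. The authors deposited TPM, a unit of abundance that divides by transcript length and scales each library to a fixed total. Each cohort has its own table with a column per library and no pooling. Both deposited tables hold 55804 gene rows. The AppNLGF table holds another 64708 rows of single transcripts, which were kept out of the gene comparisons. Gene rows hold 88.5 to 91.4% of the fixed total in the AppNLGF libraries, and transcript rows the rest. In the APP/TAU libraries gene rows hold 84.9 to 90.8%, no transcript rows are listed, and what makes up the rest is unknown.

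TPM keep no sequencing depth, so the number of reads behind each value is unknown and no counting interval can be given. Because every library is scaled to the same total, a difference in a very abundant RNA moves the values of all other genes the other way. A single gene row, ENSMUSG00000118866, takes 15.5 to 40.0% of the TPM of a library, and this RNA has no symbol in the gene names used here. For that reason each comparison was also made with TPM rescaled by the median ratio of each library to the geometric mean over all tested genes, which is called median-ratio scaling here.

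Gene symbols were matched to identifiers for 51327 of the 55804 gene rows. Gene positions are those of GENCODE M21 on GRCm38. Each library was assigned to its group by its title. Genes with a mean TPM of at least 1 over all libraries of their table were tested, 16776 in the AppNLGF table and 17592 in the APP/TAU table. Values were analysed as log2(TPM + 1), and every fold change is a difference on that scale, which understates the change of genes with low TPM. The tests across genes used limma 3.58.1 (a linear model with 1 mean per group, moderated with a trend of variance on expression) in R 4.3.3, with version 1.17.8 of data.table to read the values. All 3 groups of a cohort entered the same fit, tests were two-sided, and p was adjusted over all genes tested (Benjamini-Hochberg). A gene was called at an adjusted p below 0.05. Errors of fold changes are standard errors (SE) of that fit, and errors of TPM are standard deviations (SD) between libraries.

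Before the data were examined, 32 gene lists with 543 distinct members were fixed, together with the comparisons, the tests, the alternatives and the rule for naming genes. Of the members, 462 were tested in the AppNLGF table and 478 in the APP/TAU table, and 31 lists had the minimum of 5 tested members. Each list was tested against all other genes with camera from limma at a preset correlation between genes of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated from the data. Members of a list were counted after adjustment over all genes and after adjustment over the list alone. The mean log2(TPM + 1) of the NRF2 target list in each library was compared between treated and vehicle libraries with a two-sided permutation test, exact in the APP/TAU cohort and with 100000 resamples in the AppNLGF cohort. Other scores of 1 value per library were compared the same way, exactly where the splits could all be counted.

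The named genes were the 10 called genes with the largest rise and the 10 with the largest fall of each comparison, leaving out predicted and clone names, or the 5 with the smallest p where fewer than 3 genes were called; up to 4 members of each list with the smallest p; and a fixed set of NRF2, amyloid, tau and glial genes. Genes named outside that rule are said to have been chosen after their values were seen.

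The reversal of genotype differences by treatment was measured as the covariance and correlation, across genes, of the genotype fold and the treatment fold. Both folds share the vehicle libraries, which makes the relation negative by chance, so the values are given beside 100 simulations of unchanged groups and beside 100 splits of the vehicle libraries in which each part entered only 1 of the folds. Effects were compared between the cohorts in 1 fit of 6 group means over the 16418 genes tested in both tables; each fold was taken within its own table.

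The alternatives were median-ratio scaling, quantile normalization, TPM rescaled after leaving out mitochondrial and the 20 most abundant genes, a pseudocount of 0.1, a minimum mean TPM of 5 or none, robust moderation, library weights, a fit of only the groups compared, the replicate number as a block, estimated correlations and the fry test for lists, and leaving out each library in turn. Alternatives added after seeing the data left out libraries with an extreme share of the most abundant RNA or with Xist, added transcript rows to their gene, or fitted replicate numbers 1 to 5 against 6 and above.

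The steps were tested on simulated data with the real means and spreads and 200 changed genes. In the simulated AppNLGF genotype comparison of 16776 genes, 62% of genes changed by 0.5 log2 and 90% of those changed by 1 log2 were called; for the AppNLGF treatment comparison the values were 83% and 94%. For APP/TAU, over 17592 genes, they were 41% and 87% for genotype and 37% and 86% for treatment. In these 4 simulations 11, 9, 6 and 6 unchanged genes were called among 163, 186, 134 and 129 calls, and none was called when no gene was changed. All 10 simulated sets of 30 genes shifted by 0.3 were called in each comparison, and 0 of 10 unshifted sets. Each gene was drawn independently, so the simulated data hold no correlation between genes and no shift shared by all genes. They therefore cannot give the rate of false calls in the real libraries, for which splits of the libraries are given below.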

Results

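Gene expression was measured by RNA sequencing of brain tissue from 2 mouse models of Alzheimer's disease given CDDO-2P-Im, a synthetic oleanane triterpenoid that induces NRF2. NRF2 is a transcription factor that switches on antioxidant and detoxifying genes and is held back by KEAP1. AppNLGF mice carry familial disease mutations and a humanised amyloid sequence in their own App gene, and APP/TAU mice carry human APP and TAU transgenes with familial mutations. CDDO-2P-Im was given by mouth at 30 µmol/kg, 3 times per week, for 4 weeks to AppNLGF mice and for 2 weeks to APP/TAU mice. The AppNLGF cohort, 6 months old, held 4 wild type vehicle, 11 AppNLGF vehicle and 13 AppNLGF CDDO-2P-Im libraries. The APP/TAU cohort, 11 months old, held 5 libraries each of wild type vehicle, APP/TAU vehicle and APP/TAU CDDO-2P-Im. Values are the authors' TPM, which keep no depth, so the depth of each library is unknown. The labels number the libraries of a group as replicates without saying that each is a separate animal, so p-values measure the spread between these libraries.

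The labels give the tissue as brain without a region, and markers of striatum and cerebellum differed between the cohorts. The mean log2(TPM + 1) of 10 striatal markers was 5.58 ± 0.144 in wild type libraries of the AppNLGF cohort (SD, n = 4) and 3.16 ± 0.358 in those of the APP/TAU cohort (n = 5). That of 10 cerebellar markers was 1.56 ± 0.0280 and 5.45 ± 0.263. Other regions lay closer together, with 10 hippocampal markers at 2.17 ± 0.305 and 2.52 ± 0.102 and 13 thalamic and hypothalamic markers at 2.45 ± 0.642 and 2.94 ± 0.562. The thalamic and hypothalamic mean also varied between libraries of a group, from 1.13 to 3.41 in AppNLGF vehicle. Pcp2, a gene of cerebellar Purkinje cells, was at 0.283 ± 0.372 and 156 ± 23.3 TPM, and the striatal phosphoprotein gene Ppp1r1b at 185 ± 18.2 and 40.8 ± 6.47. In the vehicle and treated groups of the models the striatal means were 5.34 to 5.37 in the AppNLGF and 2.93 to 3.14 in the APP/TAU cohort, and the cerebellar means 1.52 to 1.57 and 5.52 to 5.64. These levels, with no filter on low values, and the 2 genes were chosen after the data were seen. The 2 tables were normalized separately, so the levels are set side by side without a test.

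The most abundant RNA, ENSMUSG00000118866, made up 31.7 ± 1.36% (SD, n = 4) of TPM in wild type, 33.1 ± 3.35% (n = 11) in vehicle and 33.4 ± 4.51% (n = 13) in treated libraries of the AppNLGF cohort. In the APP/TAU cohort it made up 30.1 ± 3.72% in wild type, 22.0 ± 6.59% in vehicle and 29.5 ± 1.54% in treated libraries (n = 5 each; exact permutation p = 0.0635 for vehicle against either other group). The median fold of all tested genes was accordingly +0.18 log2 for APP/TAU vehicle against wild type and -0.19 for treated against vehicle. Folds of that cohort are given below as deposited, with this shift in them, unless median-ratio scaling is named. In the AppNLGF cohort the corresponding medians were -0.026 and -0.038.

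The genes of the disease models were read out in each group first. App (chromosome 16, 84949685 to 85173766, GRCm38) was at 955 ± 102 TPM in APP/TAU vehicle and 904 ± 120 in APP/TAU treated libraries against 460 ± 70.8 in wild type (n = 5 each). Every APP/TAU library lay above every wild type library. Mapt, the tau gene (chromosome 11, 104231390 to 104332090), was at 176 ± 26.5, 144 ± 21.6 and 125 ± 23.4 TPM in the same order. In the AppNLGF cohort, where the mutations sit in the mouse gene itself, App was at 438 ± 21.2 TPM in vehicle (n = 11) and 433 ± 40.8 in treated libraries (n = 13) against 469 ± 17.9 in wild type (n = 4). Whether reads of human sequence were counted in the rows of mouse App and Mapt is not given in the sources used here.

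The comparison of AppNLGF vehicle with wild type asks what amyloid pathology changes in the brain at 6 months. Genes of microglia gathered at plaques were strongly higher. Cst7, an inhibitor of cathepsins (chromosome 2, 150570415 to 150578944), rose by 3.72 ± 0.30 log2 from 0.194 ± 0.158 to 15.0 ± 3.62 TPM (adjusted p = 6.22e-09, n = 4 and 11). The lipid receptor Trem2 (chromosome 17, 48346401 to 48354147) rose by 1.41 ± 0.17 from 7.07 ± 0.720 to 20.8 ± 4.15 TPM (adjusted p = 3.08e-05). Gfap, the intermediate filament of astrocytes (chromosome 11, 102887336 to 102900912), rose by 1.58 ± 0.20 from 45.3 ± 6.09 to 138 ± 20.8 TPM (adjusted p = 4.97e-05). All 11 vehicle libraries lay above all 4 wild type libraries for each of these genes. Against this, immediate early genes fell. Fos (chromosome 12, 85473890 to 85477273), a transcription factor induced within minutes of stimulation, was at 6.01 ± 1.70 against 22.0 ± 7.22 TPM (-1.71 ± 0.29, adjusted p = 0.00189). It was lower in 11 of 11 vehicle libraries than in every wild type library. A clock score with median-ratio scaling was also compared, after the data were seen. It is the mean of Nr1d1, Nr1d2, Dbp, Tef, Hlf, Ciart and Per3 minus the mean of Arntl, Clock and Npas2. It contrasts these clock genes and is not a level of their expression. This score was lower in these vehicle libraries than in wild type. The difference was -0.28 (exact permutation p = 0.0168). The labels give a dosing schedule for AppNLGF vehicle libraries and none for wild type libraries. Neither dosing nor the time of day at which tissue was taken is separated from genotype here, and neuronal activity was not measured.

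Over all 16776 genes, 37 rose and 10 fell. With a term for replicate numbers 1 to 5 against 6 and above, 35 rose and 166 fell, and the median fold of all genes was -0.14. All 4 wild type libraries have numbers 1 to 5, so this fit sets them against the level of vehicle libraries with those numbers. Those vehicle libraries held more of the most abundant RNA (36.3 ± 1.29%) than wild type (31.7 ± 1.36%) or vehicle libraries with higher numbers (30.5 ± 1.66%). The fit therefore cannot separate that share from genotype. The other genes with the largest rises were the chemokines Ccl6 (2.36 ± 0.27) and Ccl3 (1.87 ± 0.27), the fungal glucan receptor Clec7a (2.11 ± 0.26), the integrin Itgax (1.77 ± 0.23), lysozyme Lyz2 (1.40 ± 0.21), Cd52 (1.26 ± 0.22) and Ly86 (1.16 ± 0.19). Their adjusted p lay between 1.05e-05 and 0.00205, with all 11 vehicle libraries above wild type. The other genes that fell were Junb (-1.34 ± 0.21), Nr4a1 (-1.33 ± 0.22), Egr2 (-1.32 ± 0.29), Dusp1 (-1.27 ± 0.24), Arc (-1.24 ± 0.24), Npas4 (-1.16 ± 0.20), Ier2 (-0.80 ± 0.17), Arl4d (-0.78 ± 0.17) and the clock gene Per1 (-0.57 ± 0.12). Their adjusted p lay between 0.00105 and 0.0359, with 10 or 11 of 11 libraries below every wild type library for each. The homeostatic microglia genes P2ry12 (0.21 ± 0.19) and Tmem119 (0.18 ± 0.11), the lipid carrier Apoe (0.025 ± 0.065) and the haem oxygenase Hmox1 (0.44 ± 0.14, adjusted p = 0.404) did not pass. With median-ratio scaling 93 genes rose and 23 fell, 46 of the 47 among them; Arl4d no longer passed (adjusted p = 0.108).

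Among the lists, 14 of 31 tested genes of plaque-associated microglia rose (19 adjusted over the list alone, median fold 0.69). Among them were the cathepsins Ctsd (0.82 ± 0.14, from 127 to 226 TPM) and Ctsz (0.77 ± 0.11) and the lysosomal marker Cd68 (1.14 ± 0.21). Of 16 complement and phagocytic receptor genes 9 rose (15 adjusted over the list alone, median 0.67). All 3 chains of the complement starter C1q rose, C1qa (0.82 ± 0.14), C1qb (0.74 ± 0.13) and C1qc (0.87 ± 0.12). Of 17 reactive astrocyte genes Gfap, C4b (1.14 ± 0.18) and the protease inhibitor Serpina3n (0.88 ± 0.19) rose (7 adjusted over the list alone; median 0.26). Of 18 homeostatic microglia markers the Fc receptor genes Fcgr3 (0.79 ± 0.14) and Fcrls (0.79 ± 0.16) rose (8 adjusted over the list alone, Csf1r included; median 0.25). None of 9 antigen presentation genes passed over all genes, and B2m, H2-D1 and H2-K1 did adjusted over the list alone (median 0.45). Of 15 immediate early genes 8 fell (13 adjusted over the list alone; median -1.15). These 6 lists also passed camera with an estimated correlation, which allows for members that vary together. The adjusted p with an estimated correlation was 0.000854 for plaque-associated microglia and for immediate early genes, 0.000631 for complement, 0.00586 for reactive astrocytes, 0.0227 for homeostatic microglia and 0.0364 for antigen presentation.

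A further 10 lists passed only at the preset correlation. Genes of lysosomes and autophagy (3 of 24 rose, 8 adjusted over the list alone; adjusted p = 0.161 with an estimated correlation), endothelium (0.161), mural and meningeal cells (0.474), interferon response (0.216) and astrocyte identity (0.477) lay above other genes, the p in brackets being the adjusted p with an estimated correlation. Genes of myelin (1 of 16 lower adjusted over the list alone; 0.474), choroid plexus (0.474), striatum (0.420), blood cells (0.465) and the circadian clock (4 of 15 lower adjusted over the list alone; 0.343) lay below them, with the same p in brackets. In the blood list the leukocyte gene Ptprc rose by 0.68 ± 0.13, while 3 of the 4 haemoglobin genes were lower adjusted over the list alone, Hbb-bs at 18.9 ± 13.2 against 45.1 ± 24.0 TPM. The female-specific RNA Xist was above 10 TPM in 0 of 4 wild type and 5 of 11 vehicle libraries. With median-ratio scaling the mean of the immediate early list was also lower than in wild type in the 6 vehicle libraries without Xist. The difference was -0.96 (exact permutation p = 0.00476), as against -0.97 in all 11 (exact permutation p = 0.000733).

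With 4 wild type libraries, leaving out wild type 1 lowered the count to 22 higher and 7 lower genes, and with median-ratio scaling from 116 to 74. Single libraries decided the calls of Serpina3n (lost without wild type 1, 3 or 4, adjusted p 0.0949 to 0.167), Ier2 (wild type 1, 2 or 3, 0.0578 to 0.272), Per1 (wild type 2, 3 or 4, 0.0600 to 0.194), Arc (wild type 2 or 3, 0.0860 to 0.139), Dusp1 (wild type 2, 0.0879). The same held for Egr2 (any wild type library or vehicle 2, 3, 4, 5 or 10, 0.0509 to 0.208) and Arl4d (any wild type library or vehicle 2, 3, 5, 8 or 10, 0.0515 to 0.256). In these fits the folds kept their direction. They were 0.82 to 0.90 for Serpina3n, -0.85 to -0.67 for Ier2, -0.58 to -0.47 for Per1 and -1.17 to -1.07 for Arc. For Dusp1 the fold was -1.09, for Egr2 -1.44 to -1.22 and for Arl4d -0.85 to -0.68.

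**Figure D1:**
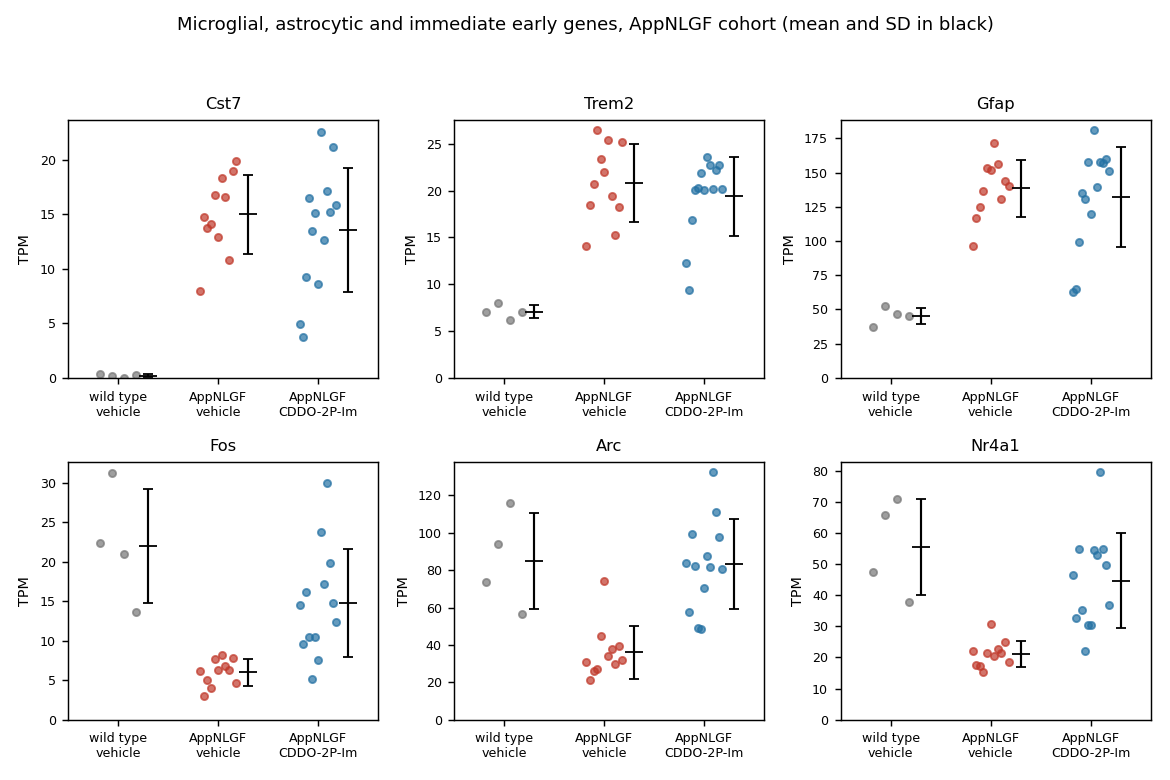
TPM of Cst7, Trem2, Gfap, Fos, Arc and Nr4a1 in each library of the AppNLGF cohort (wild type n = 4, vehicle n = 11, CDDO-2P-Im n = 13); points are libraries, and black marks are the mean and SD. All 11 vehicle libraries lie above wild type for Cst7, Trem2 and Gfap, and treated libraries average 83.2 TPM of Arc against 36.1 in vehicle.

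The comparison of treated with vehicle AppNLGF libraries asks what 4 weeks of the NRF2 inducer change in the diseased brain. Immediate early genes rose. Arc, a regulator of glutamate receptor uptake at synapses (chromosome 15, 74669083 to 74672570), rose by 1.202 ± 0.171 log2 from 36.1 ± 14.2 to 83.2 ± 23.9 TPM (adjusted p = 0.00182; 9 of 13 treated libraries above every vehicle library, n = 13 and 11). The wild type mean was 84.9 ± 25.6 TPM. Nr4a1 (chromosome 15, 101254269 to 101274795) rose by 0.99 ± 0.16 (adjusted p = 0.00264; 10 of 13), Junb (chromosome 8, 84974484 to 84978718) by 0.98 ± 0.15 (0.00264; 13 of 13) and Fos by 1.09 ± 0.20 (0.0232; 11 of 13). Aox1, an aldehyde oxidase and NRF2 target (chromosome 1, 58029931 to 58106413), rose by 0.49 ± 0.09 from 1.76 ± 0.292 to 2.90 ± 0.716 TPM (adjusted p = 0.0232; 11 of 13).

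In all, 8 genes rose and 1 fell, and 1036 of 16776 genes had an unadjusted p below 0.05 in limma. The other genes that rose were the autophagy regulator Depp1 (0.90 ± 0.14, from 0.639 ± 0.260 to 2.12 ± 0.842 TPM), Rsrp1 (0.85 ± 0.16) and the reactive imine deaminase Rida (0.44 ± 0.08, from 21.2 ± 1.33 to 29.5 ± 4.83 TPM). The redox protein Nxn fell (-0.35 ± 0.07, 12 of 13 libraries below every vehicle library). With median-ratio scaling 41 genes rose and 7 fell, 8 of the 9 among them, and Nxn missed the threshold (adjusted p = 0.0592). The glial genes raised in this model were not called after treatment: Cst7 was at -0.23 ± 0.21, Trem2 at -0.11 ± 0.12, Gfap at -0.12 ± 0.14, Clec7a at -0.17 ± 0.18 and Itgax at -0.11 (adjusted p of at least 0.807). Only treated libraries 1 and 2 lay below every vehicle library for Cst7 (4.94 and 3.78 TPM, lowest vehicle 7.93), Gfap (62.8 and 64.9, lowest vehicle 96.6) and Trem2 (12.3 and 9.40, lowest vehicle 14.1), and the negative folds rest largely on them. Of 31 plaque-associated microglia genes, 0 passed over all genes or adjusted over the list alone.

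Of 35 tested NRF2 target genes, Aox1 rose over all genes and Gstm1 (0.46 ± 0.10), Nqo1 (0.44 ± 0.10) and the ferritin light chain Ftl1 (0.22 ± 0.06) also did adjusted over the list alone. Nqo1, the quinone reductase used as the standard readout of NRF2 (chromosome 8, 107388225 to 107403206), was at 3.63 ± 0.824 against 2.39 ± 0.572 TPM, above every vehicle library in 6 of 13 treated libraries, and missed the threshold over all genes (adjusted p = 0.157; 0.0247 without treated library 4). With median-ratio scaling 4 members rose over all genes, Gstm1 by 0.50 ± 0.06 (adjusted p = 0.000104), Ftl1 by 0.27 ± 0.04 (0.000121), Aox1 by 0.52 ± 0.09 (0.00523) and Nqo1 by 0.47 ± 0.10 (0.0269). Adjusted over the list alone 8 did, while Gclm (0.085 ± 0.075), Hmox1 (0.023 ± 0.085) and Srxn1 (0.024 ± 0.045) did not pass. The list as a whole lay above other genes with a median fold of 0.069 (camera adjusted p = 1.26e-10; adjusted p = 0.762 with an estimated correlation, and 0.0173 with both an estimated correlation and median-ratio scaling). The mean of the list per library was 4.16 ± 0.168 in treated and 4.06 ± 0.0897 in vehicle libraries, a difference of 0.10 that missed the threshold (permutation p = 0.0890, above the vehicle median in 8 of 13) except without treated library 1 (0.12). With median-ratio scaling it was 0.14 (4.18 ± 0.0560 against 4.04 ± 0.0761, permutation p = 5e-05, above the vehicle median in 13 of 13).

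Of the 15 immediate early genes 4 rose over all genes and 11 adjusted over the list alone (median 0.58; adjusted p = 0.00699 with an estimated correlation), Dusp1 (0.81 ± 0.17), Ier2 (0.58 ± 0.12) and Egr2 (0.93 ± 0.20) among them. The mean of this list with median-ratio scaling was higher by 0.65 (permutation p = 3e-05, 12 of 13 treated libraries above every vehicle library), by 0.85 among the 12 libraries without Xist (exact permutation p = 0.00216) and by 0.49 among the 12 with it (exact permutation p = 0.00884). Xist was above 10 TPM in 7 of 13 treated and 5 of 11 vehicle libraries. Libraries with replicate numbers 1 to 5 held more of the most abundant RNA (37.5 ± 3.24% treated, 36.3 ± 1.29% vehicle) than those with higher numbers (30.8 ± 3.02% and 30.5 ± 1.66%). Within numbers 1 to 5 the immediate early difference was 0.69 (exact permutation p = 0.0238, 5 and 5 libraries) and within the higher numbers 0.61 (exact permutation p = 0.000999, 8 and 6). The NRF2 difference with median-ratio scaling was 0.10 (exact permutation p = 0.0476) and 0.17 (exact permutation p = 0.000666), and as deposited 0.0010 (exact permutation p = 0.968) and 0.15 (exact permutation p = 0.0236).

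The other lists that passed camera did so only at the preset correlation: endothelial (0.762), cholesterol synthesis (0.939) and mitochondrial genome genes (0.939) above other genes, and homeostatic microglia (0.939), astrocyte identity (0.939) and heat shock genes (0.939) below them, the p in brackets being the adjusted p with an estimated correlation. The astrocyte genes Ntsr2 (-0.19 ± 0.06) and Gjb6 (-0.29 ± 0.09) passed only adjusted over the list alone.

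The count was 5 without vehicle 3 or treated 11, 15 without treated 5 and 14 without treated 6. With median-ratio scaling the 48 became 81 without treated 4 and 89 without treated 6. Leaving out 1 library at a time ended the calls of Fos (6 libraries: vehicle 2, 3, 4 or 11, treated 3 or 11, with adjusted p 0.0511 to 0.0586) and Aox1 (5: vehicle 2, 3, 4 or 5, treated 11, with 0.0511 to 0.0586). It also ended those of Nxn (8: vehicle 3, 5, 6, 7 or 10, treated 3, 10 or 11, with 0.0502 to 0.0708) and Rsrp1 (12: vehicle 1, 2, 3, 9, 10 or 11, treated 3, 8, 9, 10, 11 or 12, with 0.0502 to 0.0742). The folds in these fits were 1.01 to 1.07 for Fos, 0.45 to 0.48 for Aox1, -0.35 to -0.32 for Nxn and 0.78 to 0.84 for Rsrp1.

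Of the 47 genes that differed between vehicle and wild type, 42 moved in the opposite direction with treatment. Because these genes were chosen by a fold that shares the vehicle libraries, opposite movement is also produced with no effect. The 10 genes lower in vehicle than in wild type were all higher in treated than in vehicle libraries (median fold 0.87), and Fos, Arc, Nr4a1 and Junb passed both tests in opposite directions. Of the 37 genes higher in vehicle than in wild type, 32 were lower with treatment, with a median of -0.09, but only 33.4% of all genes were higher with treatment, and the median of all genes was -0.038. With median-ratio scaling 89 of 116 genes moved in the opposite direction, 67 of 93 higher genes with a median of -0.053 and 22 of 23 lower genes with a median of 0.44. In a test added after seeing the data, genes were called from 1 part of the vehicle libraries and treatment folds taken against the rest. An average of 97.8% of lower genes were higher with treatment over the 72 of 100 splits that called any (92.1% with median-ratio scaling). These percentages rest on few genes, since a split called 2.17 lower genes on average (11.09 with median-ratio scaling). All splits draw on the same vehicle libraries. Of the higher genes, 83.7% were lower with treatment against 65.3% of all genes, and 68.7% against 50.8% with median-ratio scaling. Across all 16776 genes, which are not independent replicates, the folds correlated at r = -0.37 with a covariance of -0.015. Unchanged groups sharing the same vehicle libraries gave -0.38 and -0.013 on average, and 27 of 100 simulations a covariance as low. With the vehicle libraries split between the folds, r averaged -0.040 (-0.11 to 0.068 over 100 splits).

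In the APP/TAU cohort, vehicle libraries were compared with wild type to see what the transgenes change at 11 months. Thy1, a surface glycoprotein of neurons whose promoter is widely used to drive transgenes (chromosome 9, 44043384 to 44048579), rose by 1.54 ± 0.12 log2 from 250 ± 38.4 to 727 ± 62.7 TPM (adjusted p = 5.06e-06, 5 of 5 libraries above wild type), and by 1.33 ± 0.10 with median-ratio scaling. Whether the transgenes carry Thy1 sequence that was counted in the Thy1 row is not given in the sources used here. App rose by 1.06 ± 0.11 (adjusted p = 0.000333, 5 of 5) and by 0.85 ± 0.08 with median-ratio scaling. The 2 other genes called, both chosen here after their values were seen, were the pseudogene Gm15920, a copy of Ndufa12, at 26.5 ± 7.39 against 0.659 ± 0.627 TPM (4.10 ± 0.27; 3.93 ± 0.30 with median-ratio scaling), and Gm9855, a copy of Tdg, at 3.53 ± 0.750 TPM and listed at 0 in wild type. Reads shared with the parent genes make both uncertain, since 84.9% of the 31-base words of Gm15920 also occur in Ndufa12 and 83.4% of those of Gm9855 in Tdg.

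Beyond these 4 of 17592 genes nothing passed as deposited, although 4186 had an unadjusted p below 0.05 in limma and 89.9% of genes were higher in vehicle. Mapt was at 0.50 ± 0.13 (adjusted p = 0.121) and at 0.30 ± 0.08 with median-ratio scaling (adjusted p = 0.176). No glial gene was called: Gfap was at 0.08 ± 0.17, Trem2 at -0.07 ± 0.12, Serpina3n at 0.10 ± 0.16, Apoe at -0.04 ± 0.06 and P2ry12 at -0.19 ± 0.08 with median-ratio scaling, as against 0.29 ± 0.19, 0.11 ± 0.15, 0.29 ± 0.19, 0.17 ± 0.12 and 0.0029 ± 0.12 as deposited. Vehicle library 1 was the highest of its group for Gfap (174 TPM, others 76.7 to 117), Trem2 (8.56, others 4.01 to 6.61) and Cst7 (2.01, others 0 to 0.406), and without it the deposited folds of Gfap and Trem2 were 0.11 and -0.0038. Ndufa12, a subunit of respiratory complex I (chromosome 10, 94198720 to 94221443), fell by 0.51 ± 0.06 with median-ratio scaling (adjusted p = 0.00360), the only call added by it.

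Among the lists, mitochondrial genome and immediate early genes lay above other genes and NRF2 target, choroid plexus, striatal, thalamic and hypothalamic, interferon response, stress response, heat shock and nuclear respiratory chain genes below them. Each of these 10 had an adjusted p = 0.975 with an estimated correlation. Of 13 mitochondrial genome genes none passed over all genes and 10 did adjusted over the list alone, mt-Atp8 at 0.71 ± 0.18; with median-ratio scaling none did (mt-Atp8 at 0.50 ± 0.19). Of the amyloid and tau list App, Mapt and Lrp1 passed adjusted over the list alone, App alone over all genes. The NRF2 list had a median of 0.10, which lies -0.078 from that of all genes, and 0 of 36 members passed. The 4 haemoglobin genes averaged higher in vehicle libraries, Hbb-bs at 66.6 ± 60.2 against 11.5 ± 4.53 TPM, without passing (adjusted p = 0.148). For Hbb-bs this rests largely on vehicle 3 and 4 (146 and 116 TPM). Vehicle 1 and 2 were at 35.3 and 25.7, and vehicle 5 at 10.3 lay within the wild type range of 5.07 to 17.8.

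The gene count was 8 without vehicle 3 and 7 without vehicle 5, each with the same 4 genes among them, and 5295 with library weights. With median-ratio scaling the 5 became 8 without wild type 1 and 14 (9 higher, 5 lower) without vehicle 3, the same 5 genes among them each time. The list count was 5 without wild type 5 and 6 without vehicle 3 or with median-ratio scaling.

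**Figure D2:**
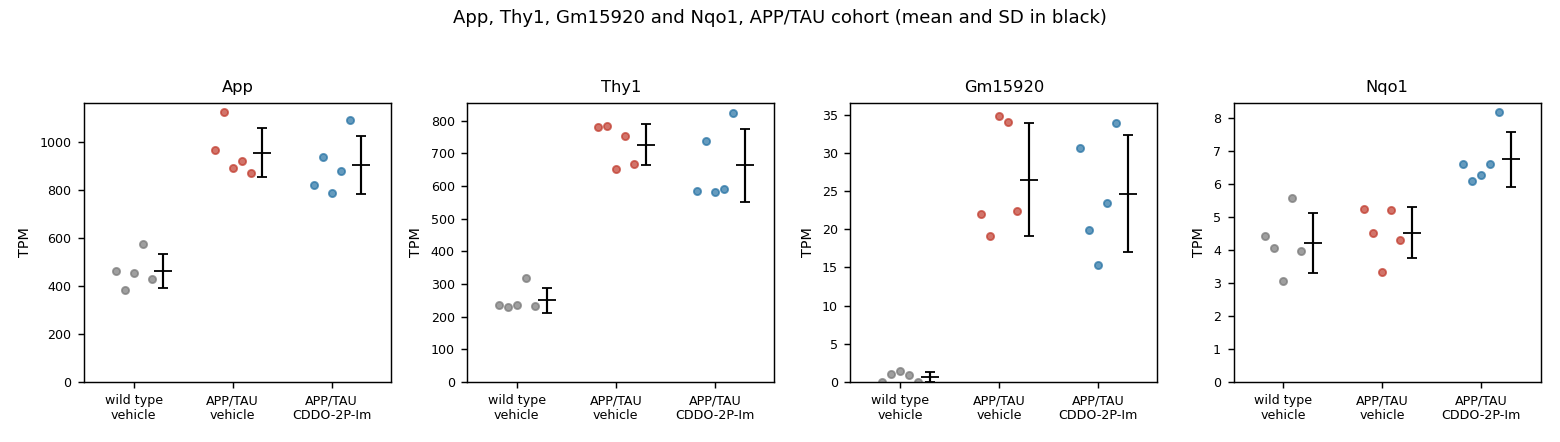
TPM of App, Thy1, Gm15920 and Nqo1 in each library of the APP/TAU cohort (wild type, vehicle and CDDO-2P-Im, n = 5 each); points are libraries, and black marks are the mean and SD. All APP/TAU libraries lie above wild type for App, Thy1 and Gm15920, and all 5 treated libraries lie above vehicle for Nqo1.

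Treated were compared with vehicle APP/TAU libraries to see what 2 weeks of the inducer change in this model. Relative to the shift of all genes, NRF2 target genes were higher. With median-ratio scaling Ftl1, the ferritin light chain (chromosome 7, 45457944 to 45459884), rose by 0.41 ± 0.04 and Gstm1, a glutathione transferase (chromosome 3, 108012255 to 108017973), by 0.64 ± 0.07 (adjusted p = 0.00117 each, n = 5 and 5). Both passed again in each of the 10 fits that left out 1 library. As deposited Gstm1 was at 185 ± 21.0 against 138 ± 14.4 TPM, 5 of 5 libraries above vehicle. Ftl1 was at 259 ± 14.6 against 227 ± 20.1 TPM, 3 of 5 above. Nqo1 was at 6.75 ± 0.837 against 4.52 ± 0.782 TPM (0.50 ± 0.13, adjusted p = 0.167, 5 of 5 above vehicle; 0.68 ± 0.11 and adjusted p = 0.112 with median-ratio scaling). Hmox1 was at 2.89 ± 0.399 against 2.20 ± 0.390 TPM (0.29 ± 0.11, adjusted p = 0.167; 0.44 ± 0.09 and adjusted p = 0.270 with median-ratio scaling).

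As deposited, limma called 0 of 17592 genes, with 4719 at an unadjusted p below 0.05 and 9.8% of genes higher in treated libraries; with median-ratio scaling it called Ftl1 and Gstm1. The 5 genes with the smallest p, none of which passed (adjusted p = 0.167), were Gm15815 (-2.47 ± 0.40), Gm29488 (-0.46 ± 0.08), Gm13091 (-0.62 ± 0.12), Spout1 (-0.999 ± 0.192, or -0.81 ± 0.22 with median-ratio scaling, at 2.89 ± 1.14 against 6.60 ± 1.14 TPM) and ENSMUSG00002076470, at 56.9 ± 40.8 TPM in treated libraries and listed at 0 in all 5 vehicle libraries. Without vehicle 5 the count was 2. Without treated 3 it was 1 (Gm15815, adjusted p = 0.0339), without treated 5 it was 1 (ENSMUSG00002076470, adjusted p = 2.27e-10). With library weights it was 7298. With median-ratio scaling the 2 became 4 without vehicle 5.

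Of 36 NRF2 target genes 0 passed over all genes and 2, Nqo1 and Gstm1, adjusted over the list alone. With median-ratio scaling 16 passed adjusted over the list alone, including Aox1 (0.63 ± 0.11), Mgst1 (0.74 ± 0.21) and Gclc (0.19 ± 0.06). The list lay above other genes (camera adjusted p = 7.40e-13; adjusted p = 0.944 with an estimated correlation, and 0.0263 with both an estimated correlation and median-ratio scaling), although its median was -0.029 and its mean 0.035, because all genes lay at -0.19. The mean of the list per library was 4.28 ± 0.0710 in treated and 4.25 ± 0.139 in vehicle libraries (difference 0.035, exact permutation p = 0.635; -0.0093 without vehicle 3). With median-ratio scaling it was 4.35 ± 0.0562 against 4.11 ± 0.0409, a difference of 0.24, with 5 of 5 treated libraries above every vehicle library and the smallest p that 5 against 5 libraries allow (exact permutation p = 0.00794).

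Immediate early genes were lower in this model. Of 15, none passed over all genes and 11 did adjusted over the list alone, Arc at -0.68 ± 0.14 (49.1 against 80.1 TPM) and Egr1 at -0.60 ± 0.12 (list median -0.50; adjusted p = 0.944 with an estimated correlation). With median-ratio scaling Arc was at -0.46 ± 0.12 and Egr1 at -0.38 ± 0.09, 8 passed adjusted over the list alone, and the mean of the list was lower by -0.29 with 5 of 5 treated libraries below every vehicle library (exact permutation p = 0.00794). Circadian clock genes (10 of 15 lower adjusted over the list alone, Per3 at -0.44 ± 0.11), mitochondrial genome genes (5 of 13, mt-Nd6 at -0.51 ± 0.11) and neuronal markers (0 of 22) lay below other genes and interferon response genes above them, each with an adjusted p = 0.988 with an estimated correlation. With median-ratio scaling 0 of the 15 clock genes (Per3 at -0.23 ± 0.09) and 1 of the 13 mitochondrial genome genes (mt-Nd6 at -0.28 ± 0.07) passed adjusted over the list alone. Across 17592 genes the treatment folds correlated with the genotype folds at r = -0.57 with a covariance of -0.041. Unchanged groups gave -0.52 and -0.035 on average, and 28 of 100 simulations a covariance as low (-0.051 without vehicle 3 and -0.059 without vehicle 5). With the vehicle libraries split between the folds r averaged -0.065 (-0.10 to -0.014 over 100 splits).

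**Figure D3:**
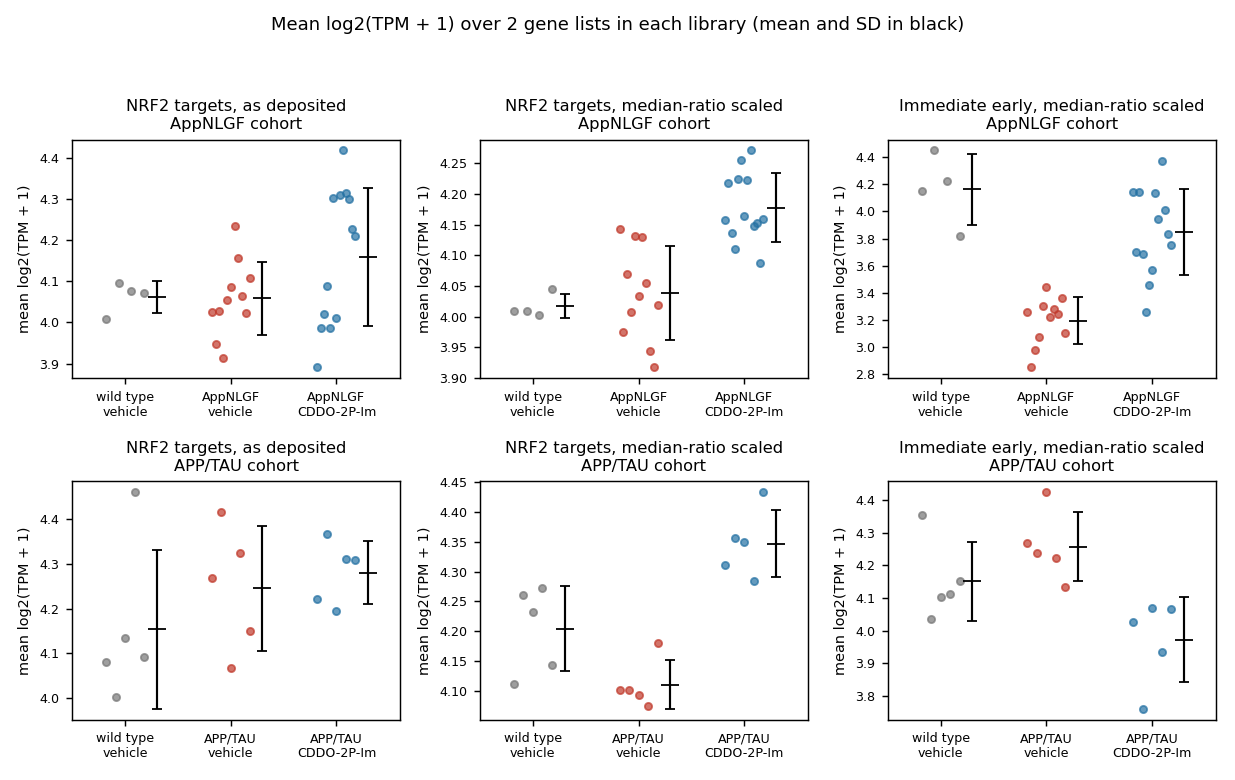
Mean log2(TPM + 1) of the NRF2 target list, as deposited and with median-ratio scaling, and of the immediate early list with median-ratio scaling, in each library of both cohorts; points are libraries, and black marks are the mean and SD. With median-ratio scaling the NRF2 mean of treated libraries exceeds vehicle by 0.14 in AppNLGF and 0.24 in APP/TAU, and the immediate early mean differs by 0.65 and -0.29.

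The effects of the 2 models were compared directly over 16418 genes; model, age, weeks of treatment, regional markers and table differ together here and cannot be separated. The genotype effect differed for 29 genes, 3 of them with the higher fold in AppNLGF, and with median-ratio scaling for 88, 59 of them higher in AppNLGF. Trem2 (difference 1.30 ± 0.25, adjusted p = 0.00881), Gfap (1.30 ± 0.30, 0.0495) and Lyz2 (1.36 ± 0.30, 0.0386) had the higher fold in AppNLGF, and Thy1 (-1.54 ± 0.14), App (-1.16 ± 0.12) and Fos (-2.06 ± 0.37, adjusted p = 0.00613) in APP/TAU. The plaque-associated microglia, homeostatic microglia, complement, reactive astrocyte and immediate early lists differed with an estimated correlation as well (adjusted p 0.0188, 0.0366, 0.00265, 0.0188 and 0.0188).

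The treatment effect differed for 22 genes, 21 of them with the higher fold in AppNLGF, and with median-ratio scaling for 12, 8 of them higher. Arc (1.88 ± 0.28, adjusted p = 0.000711), Nr4a1 (1.61 ± 0.26, 0.00147), Junb (1.47 ± 0.25, 0.00296), Per1 (0.93 ± 0.16, 0.00592), Egr2 (1.62 ± 0.33, 0.0205) and Fos (1.53 ± 0.33, 0.0333) had the higher fold in AppNLGF. With median-ratio scaling the differences were 1.70, 1.43, 1.29, 0.75, 1.47 and 1.35, each past the threshold. The immediate early list differed too (adjusted p = 0.0410 with an estimated correlation). For Nqo1 (-0.21 ± 0.17), Gstm1 (-0.14 ± 0.11) and Ftl1 (-0.15 ± 0.06) the difference with median-ratio scaling did not pass (adjusted p of at least 0.319). Across the 16418 genes the treatment folds of both models correlated at r = -0.0067, and at -0.023 with median-ratio scaling. Across the 35 NRF2 target genes r was 0.71 and 0.70. Of these, 28 were higher in AppNLGF, 13 in APP/TAU and 12 in both as deposited, where independent signs would give 10.4. With median-ratio scaling 33, 33 and 31 were, where independent signs would give 31.1. Ftl1 and Gstm1 were called in both models with median-ratio scaling, where independent lists of 48 and 2 genes would share 0.00585.

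Both counts hang on single libraries. The count of genes with differing genotype effects was 13, 9 and 14 without wild type 1, 2 and 3 of the AppNLGF cohort and 16 without AppNLGF vehicle 3. It was 56, 11, 16 and 410 without wild type 1, 2, 3 and 4 of the APP/TAU cohort and 9, 275, 11 and 287 without APP/TAU vehicle 2, 3, 4 and 5. The count of genes with differing treatment effects was 10 and 11 without AppNLGF vehicle 1 and 3 and 41 and 42 without AppNLGF treated 2 and 5. It was 9, 7, 230, 6 and 414 without APP/TAU vehicle 1 to 5 and 13, 10, 8, 37 and 9 without APP/TAU treated 1 to 5.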

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

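The differences between models were planned, and the splits of the libraries and the test of shared reads were set out before their results were seen. The tests of the most abundant RNA, sex, time of day and strain variant were chosen after the result was seen.

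Some libraries lay far from the others of their group in Dixon's test, which by chance picks out about 1 in 20 groups, or 6.3 of the 126 sets of values examined; it picked out 14. Wild type 4 of the APP/TAU cohort was high for 7 of them: Serpina3n at 11.9 TPM (others 7.29 to 8.38), Gfap at 122 (75.0 to 85.3), Tmem119 at 9.28 (5.64 to 6.49), Apoe at 844 (575 to 647), Trem2 at 7.50 (4.79 to 5.29), Thy1 at 319 (230 to 236) and the mean of the NRF2 list at 4.46 (4.00 to 4.13). Its share of the most abundant RNA, 24.9%, was the lowest of its group. Wild type 2 of the AppNLGF cohort had Clec7a at 0.857 TPM (0 to 0.137) and wild type 4 Ccl3 at 0.366 (others 0). The pseudogene Gm15815 was at 16.0 in APP/TAU vehicle 4 (2.90 to 6.69) and at 1.88 in APP/TAU treated 3 (others 0). APP/TAU treated 2 had Serpina3n at 12.2 (6.79 to 8.33) and an immediate early mean of 3.77 (3.91 to 3.96), and APP/TAU treated 5 had Nqo1 at 8.20 (6.09 to 6.62).

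Differences between the models passed for genotype effects of Thy1 (-1.54), App (-1.16), Nr4a1 (-1.70), Fos (-2.06), Junb (-1.56), Dusp1 (-1.69), Npas4 (-1.42), Per1 (-0.97), Arc (-1.50), Ier2 (-1.07), Trem2 (1.30), Lyz2 (1.36) and Gfap (1.30), each value being the AppNLGF minus the APP/TAU fold. For treatment effects they passed for Arc (1.88), Nr4a1 (1.61), Junb (1.47), Per1 (0.93), Egr2 (1.62), Fos (1.53), Dusp1 (1.26) and Rsrp1 (1.32). With median-ratio scaling, which removes the shift of all genes, Dusp1 (1.08, adjusted p = 0.0858) and Rsrp1 no longer passed. Age, weeks of treatment, markers of brain region and table differ along with the model: the mean of cerebellar markers was 1.56 in AppNLGF cohort and 5.45 in APP/TAU cohort wild type libraries, and that of striatal markers 5.58 and 3.16. The AppNLGF table also lists single transcripts, of which 21076 were tested and 1 differed between vehicle and wild type. This transcript of Tyrobp, the signalling adaptor of Trem2 (ENSMUST00000207982), rose by 1.44 ± 0.23 (adjusted p = 0.0209, from 18.2 to 51.8 TPM). Of the 21076 transcripts, 925 had an unadjusted p below 0.05 in limma, less than the share of 0.05 that no difference would give.

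Each count was set against 100 splits of the libraries into groups of the same sizes, the real one included. For AppNLGF genotype 1 split, the real one, called as many genes (47, at most 2 in any other), and 1 with median-ratio scaling (116 against 5), but 15 called as many lists (16 against 20). For AppNLGF treatment 1 split did (9 against 1), and 1 with median-ratio scaling (48 against 2), but 47 called as many lists (8 against 17). For APP/TAU genotype 5 splits did (4 against 7479), 2 with median-ratio scaling (5 against 49), and 30 called as many lists (10 against 17). For APP/TAU treatment all 100 did (0 against 2), 2 with median-ratio scaling (2 against 2), and 43 called as many lists (6 against 13). For the difference of genotype effects 6 did (29 against 3371) and 1 with median-ratio scaling (88 against 39), and for the difference of treatment effects 4 (22 against 1148) and 1 (12 against 4). At the preset correlation, at least 15 of 100 splits thus called as many lists in each of the 4 comparisons. The real counts of 16, 8, 10 and 6 lists lay above the medians of the other splits, 10, 7, 8 and 5. They are therefore not beyond what unrelated groupings can give. The split with 7479 calls points to structure among the APP/TAU libraries other than the groups: it had the largest gap in the share of the most abundant RNA, 9.93 points against 8.13 for the real groups.

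The first pattern weighed is the rise of immediate early genes in treated AppNLGF libraries. A change in the most abundant RNA is excluded as the cause, since the mean of the list differed by 0.65 with median-ratio scaling (permutation p = 3e-05) and all genes together by -0.038 as deposited. Sex is excluded as well, since the difference was 0.85 among libraries without Xist (exact permutation p = 0.00216). The clock score described above, with median-ratio scaling, differed by 0.14 in the same comparison (permutation p = 0.0474). Between vehicle and wild type, where the immediate early genes were lower, that score differed by -0.28. The time of day at which tissue was taken could therefore not be excluded. An effect of CDDO-2P-Im on neuronal activity, the biological explanation that the groups offer, stays open beside it; in APP/TAU mice, whose libraries held far more of cerebellar and less of striatal markers, the list mean was lower (-0.29, exact permutation p = 0.00794).

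The second pattern is the NRF2 list in treated APP/TAU libraries, higher with scaling and not as deposited. Leaving out the most abundant gene row alone, with no other scaling, raised the difference of the list mean from 0.035 to 0.17 (exact permutation p = 0.00794, 5 of 5 treated libraries above vehicle). That rise follows largely by arithmetic from shares already known, 22.0% in vehicle and 29.5% in treated libraries. It is therefore no independent evidence for the share as the cause. The median fold of all genes was still -0.071 after the row was left out. An NRF2 response to treatment, the biological explanation, stays open, and why the share differs between the groups was not tested.

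The third pattern is Gm15920 high and Ndufa12 low in APP/TAU libraries. If reads of Ndufa12 had only been moved to its copy, the length-weighted sum of both would be unchanged. The sum differed by -0.38 ± 0.074 (SE) with the longest parent transcript and by -0.27 ± 0.079 with the shortest (exact permutation p = 0.00794 and 0.0159). For Ndufa12 alone the difference was -0.51. With either length the sum was lower than in wild type. By the limit set beforehand the test is undecided, because that limit was passed with the longest transcript only. Shared reads could still explain a part, which the test cannot tell. A strain variant near these genes that fits the reference copy better could also do it. Gm15920 was above every wild type library in 10 of 10 APP/TAU libraries. Its high values had been seen before this test was set, so the outcome does not weigh for a variant. The design cannot tell a variant from an effect of the transgenes.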

How the results depend on the processing

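The alternatives were fixed before the data were examined, except those that leave out libraries by Xist or by the most abundant RNA, that add transcript rows, or that fit replicate numbers 1 to 5 against 6 and above, chosen after the result was seen. Over 125 results and 20 settings plus 43 that leave out 1 library, 3217 values were compared. Of these, 2842 were labelled the same, 87 weaker, 38 stronger, 160 reversed and 90 moved in size. For folds and differences, the same means that direction and side of the threshold were kept, also where a gene stayed uncalled. For counts of genes and lists it means only a similar size. Single genes with 1 library left out make up 1655 of the 2842. TPM keep no depth, so what depth limits could not be measured, and a test per transcript in place of per gene was not run because the APP/TAU table is per gene and the transcript rows of the AppNLGF table come beside its gene rows. On their own, 21076 of those transcript rows were tested, with 1 called for genotype and 0 for treatment (1673 at an unadjusted p below 0.05 in limma).

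For AppNLGF genotype, 47 genes as deposited became 116 with median-ratio scaling, 118 with quantile normalization, 111 without mitochondrial and the 20 most abundant genes, 142 with library weights and 79 in a fit of only the groups compared. With a minimum mean TPM of 5, which tests fewer genes, 31 were called, and in the libraries without Xist, which are fewer, 18. A term for replicate numbers 1 to 5 against 6 and above gave 201 (35 higher, 166 lower, as against 37 and 10). All wild type libraries lie on the first side of that term. Leaving out single libraries gave 29 to 56. For AppNLGF treatment the 9 became 48, 46, 52 and 18 with median-ratio scaling, quantile normalization, rescaling and library weights, 22 with the replicate-number term (15 higher, 7 lower), 17 without the 3 treated libraries highest in the most abundant RNA, and 5 to 15 leaving out single libraries. For APP/TAU genotype the 4 became 8 with rescaling, 5295 with library weights and 4 to 8 leaving out single libraries. For APP/TAU treatment the 0 became 2 with each of the 3 scalings, 1 with median-ratio scaling without the 2 vehicle libraries lowest in the most abundant RNA, 7298 with library weights and 0 to 2 leaving out single libraries. The cause was not tested.

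The lists called, 16, 8, 10 and 6 in the 4 comparisons, became 6, 1, 0 and 0 with an estimated correlation, 4, 1, 0 and 1 with directional fry and 6, 1, 2 and 3 with mixed fry. For APP/TAU genotype, with 2 lists above and 8 below other genes, they were 6 with median-ratio scaling, 6 with rescaling and 6 with library weights, all below, 5 with no filter on low values, all above (NRF2 list adjusted p = 0.8286), and 5 to 13 leaving out single libraries. The NRF2 mean in AppNLGF treatment, 0.10 as deposited, passed at 0.14 with median-ratio scaling, 0.13 with quantile normalization, 0.15 with rescaling, 0.11 with no filter, 0.17 with median-ratio scaling in the libraries without Xist and 0.16 without the 3 treated libraries highest in the most abundant RNA; leaving out single libraries gave 0.079 to 0.12. In APP/TAU treatment, 0.035 as deposited passed at 0.24, 0.23 and 0.24 with the 3 scalings and at 0.22 with median-ratio scaling without the 2 vehicle libraries lowest in the most abundant RNA; leaving out single libraries gave -0.0093 to 0.078. The cause was not tested, apart from leaving out the most abundant RNA, which could not decide it.

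Genotype effects differed between the models for 29 genes, or 88, 81 and 65 with the 3 scalings, 13 with a minimum mean TPM of 5, 3630 with library weights and 9 to 410 leaving out single libraries. Treatment effects differed for 22, or 12 with median-ratio scaling, 13 with rescaling, 5475 with library weights and 6 to 414 leaving out single libraries. The reversal covariance of AppNLGF, -0.015, was -0.0088 with no filter and -0.038 with a pseudocount of 0.1, and that of APP/TAU, -0.041, was -0.11 with that pseudocount and -0.059 to -0.039 leaving out single libraries. The cause was not tested.

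The direction of small folds depended on the scaling, and none of the genes concerned was called with these scalings. The 3 scalings were, in this order, median-ratio scaling, quantile normalization and rescaling without mitochondrial and the 20 most abundant genes. In AppNLGF genotype, all 3 scalings turned the folds of Mapt (from -0.015 to 0.015, 0.020 and 0.012), Gclc (from -0.018 to 0.010, 0.011 and 0.0081), Srxn1 (from -0.020 to 0.0089, 0.011 and 0.0063) and Txnrd1 (from -0.022 to 0.0062, 0.012 and 0.0038). In AppNLGF genotype, median-ratio scaling and quantile normalization turned the folds of Gclm (from -0.025 to 0.0029 and 0.0065). In AppNLGF treatment, all 3 scalings turned the folds of Hmox1 (from -0.0093 to 0.023, 0.00035 and 0.021), Srxn1 (from -0.017 to 0.024, 0.028 and 0.021) and App (from -0.021 to 0.022, 0.016 and 0.018). In AppNLGF treatment, median-ratio scaling turned the folds of Thy1 (from -0.042 to 0.0013). In APP/TAU genotype, median-ratio scaling and quantile normalization turned the folds of Tmem119 (from 0.17 to -0.0070 and -0.024) and Slc7a11 (from 0.17 to -0.017 and -0.016). In APP/TAU genotype, all 3 scalings turned the folds of Apoe (from 0.17 to -0.036, -0.039 and -0.0052), Txnrd1 (from 0.15 to -0.049, -0.031 and -0.020), Gclc (from 0.14 to -0.059, -0.047 and -0.031), Prnp (from 0.11 to -0.098, -0.038 and -0.067), Trem2 (from 0.11 to -0.068, -0.091 and -0.048), Nqo1 (from 0.087 to -0.081, -0.11 and -0.064), Gclm (from 0.086 to -0.11, -0.093 and -0.086), Nfe2l2 (from 0.051 to -0.14, -0.14 and -0.12) and P2ry12 (from 0.0029 to -0.19, -0.19 and -0.17). In APP/TAU treatment, all 3 scalings turned the folds of Gclc (from -0.024 to 0.19, 0.18 and 0.17), Txnrd1 (from -0.035 to 0.18, 0.18 and 0.16), Trem2 (from -0.049 to 0.14, 0.14 and 0.14), App (from -0.083 to 0.14, 0.077 and 0.12), Srxn1 (from -0.088 to 0.13, 0.13 and 0.11), P2ry12 (from -0.097 to 0.11, 0.10 and 0.092), Gfap (from -0.11 to 0.11, 0.087 and 0.089), Keap1 (from -0.11 to 0.10, 0.093 and 0.083), Thy1 (from -0.14 to 0.082, 0.051 and 0.059), Apoe (from -0.16 to 0.063, 0.026 and 0.040), Nfe2l2 (from -0.18 to 0.021, 0.014 and 0.00013) and Prnp (from -0.19 to 0.035, 0.00013 and 0.013). The first 2 scalings centre all genes by construction, and the last left a median fold of all genes of 0.026 in APP/TAU genotype and -0.018 in APP/TAU treatment.

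Library weights turned the folds in AppNLGF treatment of Hmox1 (0.044), Srxn1 (0.064), App (0.021), Serpina3n (0.059), Thy1 (0.021), Prnp (0.018), Trem2 (0.00091), Itgax (0.062), Gfap (0.046), Clec7a (0.0071) and Cst7 (0.0032), in APP/TAU genotype of P2ry12 (-0.0065), in APP/TAU treatment of Txnrd1 (0.015). The cause was not tested.

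With the replicate number as a block, AppNLGF genotype called 29 genes and AppNLGF treatment 4, and folds turned in AppNLGF genotype of P2ry12 (-0.021), Apoe (-0.069) and Thy1 (-0.11) and in AppNLGF treatment of Apoe (-0.0046). The labels name no pairing by number, and the highest correlation between libraries of the same number was 0.118. Of the pairs of AppNLGF vehicle and treated libraries, 3 of 11 exceeded 0.1 and 2 of 11 correlated best with their own number. Median correlations of same-number pairs exceeded those of other pairs for AppNLGF vehicle and treated (0.054 and 0.0012) and wild type and treated libraries (0.032 and -0.0020). The same held for APP/TAU wild type and treated libraries (0.072 and -0.013). They were lower for wild type and vehicle libraries of AppNLGF (-0.021 and 0.0060) and APP/TAU (-0.012 and 0.00040), and for APP/TAU vehicle and treated libraries (-0.0096 and 0.0053). The cause was not tested.

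Leaving out each library in turn, folds close to 0 took both signs for some genes. In AppNLGF genotype they were Thy1 (-0.029 to 0.041), Mapt (-0.032 to 0.0039), Gclc (-0.043 to 0.0097), Srxn1 (-0.055 to 0.031), Txnrd1 (-0.067 to 0.016), Gclm (-0.076 to 0.051) and Slc7a11 (-0.075 to 0.057). In AppNLGF treatment they were Apoe (-0.0057 to 0.034), Hmox1 (-0.044 to 0.028), Srxn1 (-0.036 to 0.010) and Serpina3n (-0.091 to 0.023). In APP/TAU genotype they were Trem2 (-0.0038 to 0.23), Gclm (-0.016 to 0.16), Nfe2l2 (-0.028 to 0.14) and P2ry12 (-0.086 to 0.083). In APP/TAU treatment they were Gclm (-0.024 to 0.15), Slc7a11 (-0.029 to 0.077), Gclc (-0.073 to 0.013), Txnrd1 (-0.084 to 0.043), Trem2 (-0.17 to 0.064) and Gfap (-0.23 to 0.066). No gene here was called in any of these fits.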

Other observations

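Gm15920 and Gm9855, both called in APP/TAU vehicle against wild type, were also read in the other groups, a choice made after the data were seen. Gm15920 averaged 26.5 ± 7.39 TPM in APP/TAU vehicle and 24.7 ± 7.66 in APP/TAU treated libraries (n = 5 each), as against 1.04 ± 1.16 in AppNLGF vehicle libraries (n = 11). Gm9855 averaged 3.53 ± 0.750 and 3.88 ± 1.39 TPM in the same APP/TAU groups and 0.021 ± 0.069 in AppNLGF vehicle libraries, while its parent Tdg was at 8.69 ± 1.27 and 6.77 ± 1.23 in the APP/TAU groups against 9.74 ± 1.67 in wild type. The mean of the blood list with median-ratio scaling, also compared after the data were seen, was lower in AppNLGF vehicle than in wild type libraries. The difference was -1.002 (exact permutation p = 0.0352, n = 11 and 4). This mean differed by 0.043 between treated and vehicle libraries (permutation p = 0.895, n = 13 and 11).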
